A study of Homo sapiens with 2 samples.

How the data were processed

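Poly(A)-selected RNA of K562 cells, a human chronic myeloid leukemia line with erythroid features, was sequenced in 2 libraries. Both came from cells that carry dCas9-KRAB, a nuclease-dead Cas9 fused to a transcriptional repressor domain, which lowers transcription at the promoter named by a guide RNA (CRISPR interference). One library had a control guide and the other a guide against SMC1A, a core subunit of the cohesin ring. Per the labels' protocols, guides were delivered by lentivirus, cells were selected with 1 µg/ml puromycin from day 2 to day 6, cells with high blue fluorescence from the guide vector were sorted, 1 µg of RNA entered a strand-preserving library kit, and reads were paired and 100 bases long.

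The authors deposited 1 table of estimated counts per gene, not scaled between the libraries. Per the submitters' processing notes, STAR 2.7.10a, Salmon 1.10.1 and DESeq2 1.42.1 were used with genome build hg38 (GRCh38). The deposited counts are named as merged gene counts of Salmon. The roles of the other tools and the gene annotation are not given in the sources used here. The estimated counts in the deposited table are whole numbers, so the fractional estimates that Salmon gives had been rounded before deposit. Salmon divides reads that match several transcripts between them, so the counts of near-identical genes and of readthrough genes depend on that division. The table has 62702 rows: 62700 Ensembl gene identifiers, each of which has an entry in the gene-name table used here, and 2 rows named for fluorescent reporters. Coordinates and gene types were taken from GENCODE release 29 (GRCh38), which is on the build named in the notes but is not the annotation of the table. It held 97.9% of the genes with at least 100 counts.

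The library totals were 18349209 counts with the control guide and 16864207 with the SMC1A guide. Library sizes were scaled with TMM factors (edgeR 4.0.16 in R 4.3.3), and log2 ratios of CPM (counts relative to the scaled library size), SMC1A guide over control guide, were computed with edgeR's formula and a prior count of 1. The other calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. With 1 library per guide there is no replicate, so no test across samples was possible and no p-value is given. The differences are between these libraries and have no replicate check. Each ratio has an exact (Clopper-Pearson) 95% interval of the ratio of the counts. These intervals, and those of shares of the total, cover counting error only. They include no variation between cultures, and reads without molecular identifiers are not independent molecules. A count of 0 allows up to 3 counts, which is 0.171 CPM with the control guide and 0.170 CPM with the SMC1A guide.

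Genes with at least 100 counts summed over both libraries were sorted by a fixed rule of size, at least 2-fold higher or at least 2-fold lower. The named genes were SMC1A, the 12 highest and 12 lowest protein-coding genes among those with at least 500 counts, and in each gene list the 2 highest and 2 lowest members with at least 100 counts. All globin and cohesin genes with 100 counts were also named. A few list members that the rule picks are left out of the text. The 27 gene lists, the rule and the alternatives were set before the data were examined. Genes named outside the rule are said to have been chosen after their values were seen. A list was summarised by the median log2 ratio of its members with at least 20 counts. That median was placed as a percentile among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these libraries and is not a test of the conditions. The lists share some genes, and 1 name of the lists had no row of its own because it is an older symbol of another member.

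The steps were checked on counts simulated for this comparison from the real gene means and library sizes. The draws held counting (Poisson) error only. Unchanged genes had the same mean in both libraries, without the spread of the real log2 ratios (standard deviation 0.64). The results that follow therefore check the calculation and do not give error rates for the real data. Known changes were given to 200 genes, drawn from the 11321 with at least 100 counts in the real data, and the filter of 100 counts was then applied to the simulated counts. All 50 genes made 3-fold higher and all 46 made 3-fold lower that kept 100 counts passed the 2-fold rule, as did 0 of 50 genes made 1.5-fold higher, 2 of 49 made 1.5-fold lower and 0 of 11130 unchanged genes. The 95% intervals held the true fold of 95.5% of the 200 genes. Of 50 simulated lists of 20 genes shifted by 0.3 on the log2 scale, 50 lay past percentile 97.5, and 4 of 50 unshifted lists lay outside percentiles 2.5 to 97.5. Alternatives were other scalings (DESeq2 1.42.0 size factors, library totals, upper quartile, and TMM without mitochondrial and globin genes), prior counts of 0.25 and 5, and other count filters. They also included protein-coding genes alone and the counting interval wholly past 2-fold. Alternatives chosen after seeing the data were the removal of trends with GC content and transcript length or with expression level, all settings for the reporter rows, and the sums of near-identical globin copies.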

Results

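RNA levels were measured in 2 libraries of K562 cells with dCas9-KRAB, 1 with a control guide and 1 with a guide against SMC1A. The titles of both give the cells as WT. Both carry a genotype label, E50 with dCas9-KRAB, in which the labels do not explain E50. The series concerns distal genes that share an enhancer and a small topological domain, and this part measured RNA in cells depleted of SMC1A. The control library held 18349209 counts and the SMC1A library 16864207, with at least 1 count in 19468 and 20786 genes. Mitochondrially encoded genes took 9.81% of the control counts (exact 95% interval 9.80 to 9.83) and 10.6% with the SMC1A guide (10.57 to 10.60). Each guide had 1 library, so every difference below is between 2 libraries and its interval covers counting error only.

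SMC1A itself (ENSG00000072501.19, chromosome X, 53374149 to 53422728, GRCh38) was the target of the guide. Its level was 460.4 CPM (8077 counts) with the control guide and 16.3 CPM (288 counts) with the SMC1A guide, so that 3.55% of the control level was left (95% counting interval 3.14 to 3.99). The log2 ratio was -4.81. Of the 11321 genes with at least 100 counts, 2 had a lower ratio, both without a gene symbol and at 0 counts in the SMC1A library. STAG1, which encodes one of the alternative subunits bound to the cohesin ring, was 2.40-fold higher (45.4 and 109.2 CPM, log2 ratio 1.26, interval 1.15 to 1.39). STAG3, a related gene chosen after its value was seen, had 22 and 54 counts (log2 ratio 1.25). The other ring genes lay near their control level, with log2 ratios of -0.15 for SMC3, -0.03 for RAD21 and 0.18 for STAG2. The sign for RAD21 turned when libraries were scaled by their totals alone (0.10). The loader gene NIPBL had a ratio of 0.38 and its partner MAU2 0.14, the release factors WAPL and PDS5A -0.17 and -0.30, PDS5B 0.40, and the boundary protein gene CTCF -0.08, or 0.05 by library totals. The acetyltransferase genes ESCO1 and ESCO2 were at 0.01 and -0.22, the deacetylase gene HDAC8 at 0.07, CDCA5 at -0.41, SGO1 at 0.02, ESPL1 at 0.19 and PTTG1 at 0.39. The 19 measured genes of the cohesin list, SMC1A among them, had a median of 0.02 and a mean of -0.10, and the median lay at percentile 90.4 of matched random lists. In the list of condensin and SMC5/6 genes, which encode the related ring complexes, 0 of 13 genes passed 2-fold, from NSMCE1 at -0.59 and NSMCE4A at -0.45 to NCAPD2 at 0.16 and SMC4 at 0.18. Its median was -0.12, at percentile 54.0, and 0.01 by library totals.

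Genes beside the target on chromosome X were compared to see whether the repressor reached past SMC1A. Of 6 measured neighbours 0 passed 2-fold, and their median log2 ratio was 0.02 (percentile 78.1). HSD17B10 (53431258 to 53434373) was at -0.36 (interval -0.46 to -0.26). KDM5C (53191321 to 53225422) was at -0.09, or 0.04 by library totals. PHF8 (53936676 to 54048958) was at 0.22 and TSPYL2 (53082367 to 53088540) at 0.90. The remaining measured neighbours, HUWE1 and IQSEC2, were at 0.07 and -0.03 and were named after their values were seen. RIBC1 (53422690 to 53431120), which starts on the opposite strand within the SMC1A span, at its 5′ end, had 9 counts with the control guide and 0 with the SMC1A guide, so that the 95% counting interval of its fold reached up to 0.504 of the control level. It had too few counts for the list and was named after its counts were seen. HSD17B10 and RIBC1 lie nearer to SMC1A than KDM5C, TSPYL2 and PHF8 do, and both were lower. The list median therefore cannot show whether the repressor had a short reach past SMC1A.

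Across the transcriptome, 579 genes (5.11%) were at least 2-fold higher and 263 (2.32%) at least 2-fold lower with the SMC1A guide, while 8919 (78.8%) stayed within 1.5-fold. These counts depended on the filter, with 1361 higher and 518 lower among genes with at least 20 counts and 199 and 140 among those with at least 500. The whole counting interval lay past 2-fold for 343 higher and 143 lower genes. The 4-fold limit was passed by 127 higher and 39 lower genes. Higher genes made up 68.8% of those past 2-fold, against 79.7% (766 higher and 195 lower) when the libraries were scaled by their totals and 57.5% (468 and 346) when the trend with expression level was removed. In the fifth of genes with the lowest expression, 352 were higher and 113 lower, and in the fifth with the highest expression 24 were higher and 31 lower. Scaling by totals moved the median log2 ratio of all tested genes by 0.13, and ratios are given relative to the TMM scale.

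**Figure D1:**
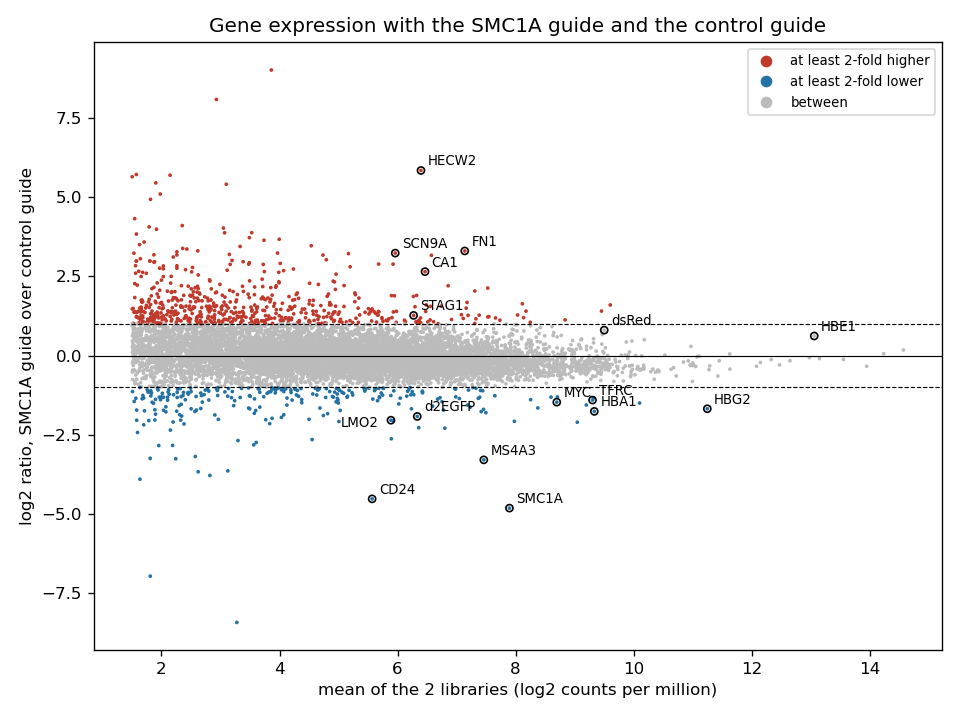
Log2 ratio of each gene with at least 100 counts (SMC1A guide over control guide) against its mean level in log2 CPM; each point is a gene, red and blue points are at least 2-fold higher or lower, and dashed lines mark 2-fold. SMC1A lies at -4.81 and HECW2 at 5.83, and of the labelled globin genes HBE1 lies above 0 while HBG2 and HBA1 lie below -1.

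Among well-measured protein-coding genes, HECW2, which encodes a HECT-type ubiquitin ligase, had the highest ratio. It stood at 2.85 CPM with the control guide and 165.8 CPM with the SMC1A guide, 58.2-fold higher (log2 ratio 5.83, interval 5.46 to 6.30; chromosome 2, 196189099 to 196593692). C6orf132 (log2 ratio 3.67), the receptor tyrosine kinase gene FGFR1 (11.2-fold) and the extracellular matrix gene FN1 followed, FN1 with 26.0 and 255.9 CPM (9.85-fold, log2 interval 3.16 to 3.44). The sodium channel gene SCN9A was 9.41-fold higher, NDRG1 9.55-fold, CRYBG1 9.34-fold, the transcription factor genes SOX5 and ETV1 9.06-fold and 8.18-fold, TMEM273 8.96-fold, HRC 7.58-fold and the spectrin gene SPTAN1 7.41-fold. At the other end, after SMC1A, stood CD24, a surface glycoprotein gene, with 91.1 and 3.91 CPM (23.3-fold lower, log2 interval -4.91 to -4.19). MS4A3, a gene of myeloid progenitors, had 320.1 and 32.7 CPM and was 9.80-fold lower (log2 interval -3.42 to -3.17). EHD2 was 6.33-fold lower and AKR1C1, a steroid-converting enzyme gene with close paralogs, 6.19-fold. HBA2 (4.90-fold), GPAT3 (4.47-fold), GALM (4.25-fold), the protein kinase C gene PRKCB (4.22-fold), DDIT4 (4.16-fold), the erythroid cofactor gene LMO2 (4.12-fold) and DHRS3 (4.05-fold) completed the 12 lowest.

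Globin genes, the main erythroid products of K562 cells, did not move as a block. Of the 8 measured, 5 were at least 2-fold lower and 0 at least 2-fold higher, and the median log2 ratio was -1.53, below all 10000 matched random lists (percentile 0). In the alpha cluster on chromosome 16, HBZ was at 878.5 and 297.7 CPM (log2 ratio -1.56), HBA1 at 997.8 and 294.1 (-1.76), HBA2 at 185.4 and 37.8 (-2.29) and HBQ1 at 13.2 and 7.14 (-0.88). In the beta cluster on chromosome 11, the fetal genes HBG2 and HBG1 were at -1.68 and -1.50. The embryonic gene HBE1 was higher, at 6755 and 10348 CPM (log2 ratio 0.62, interval 0.60 to 0.63). HBE1 counts per HBG1 and HBG2 count were 1.27 with the control guide and 5.97 with the SMC1A guide. The copies HBA1 and HBA2, and HBG1 and HBG2, are nearly identical, so the split of reads within each pair is uncertain. Their summed counts gave log2 ratios of -1.83 (interval -1.88 to -1.79) and -1.62 (-1.64 to -1.60). In the annotation the spans of HBE1 and HBG2 overlap.

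The table also holds 2 fluorescent reporter rows, d2EGFP with an SV40 poly(A) signal and dsRed-Express2, which were singled out after their values were seen. The labels do not describe where the reporters sit or what drives them. d2EGFP stood at 127.7 CPM (2241 counts) with the control guide and 33.7 CPM (594 counts) with the SMC1A guide, 3.79-fold lower (log2 ratio -1.92, interval -2.06 to -1.79). dsRed stood at 529.3 CPM (9287 counts) and 921.9 CPM (16260 counts), 1.74-fold higher (log2 ratio 0.80, interval 0.76 to 0.84). Within a library, which needs no scaling, there were 4.14 dsRed counts per d2EGFP count with the control guide and 27.4 with the SMC1A guide.

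**Figure D2:**
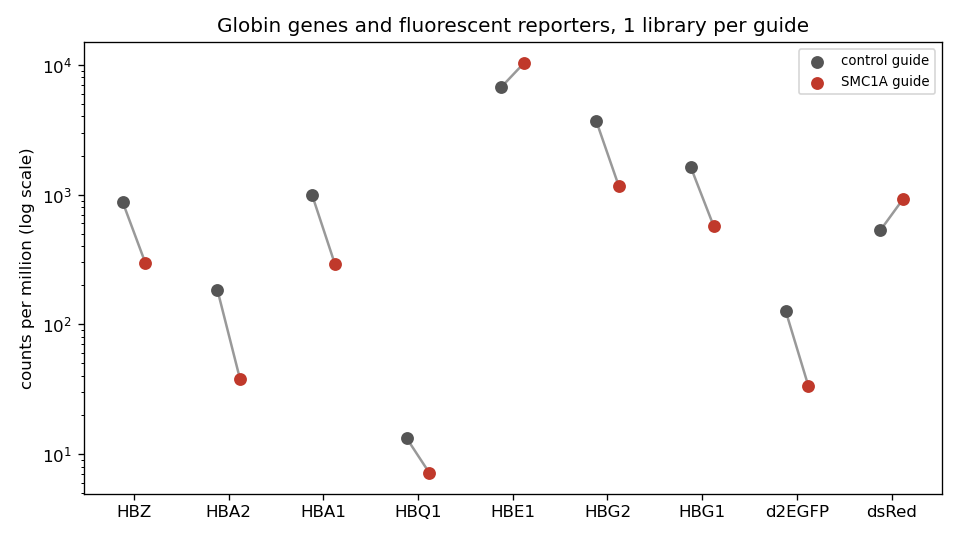
Level of 7 globin genes and 2 reporters in CPM on a log axis; each grey point is the control library, each red point the SMC1A library, and a line joins the same gene. HBE1 and dsRed are higher with the SMC1A guide (log2 ratios 0.62 and 0.80), and the other 7 are lower.

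Genes of the red cell surface and skeleton differed in the direction opposite to most globin genes. Of 23 measured, 9 were at least 2-fold higher and 2 at least 2-fold lower, with a median log2 ratio of 0.51, above all matched random lists (percentile 100.0). The carbonic anhydrase gene CA1 was 6.26-fold higher (24.3 and 152.5 CPM), and the blood group gene RHCE 3.03-fold. RHCE has a near copy in RHD, so the split of reads between them is uncertain. RHAG, at 386.1 and 1020 CPM, and KEL, at 111.3 and 258.7 CPM, were also higher, with log2 ratios of 1.40 and 1.22. Both were chosen after their values were seen. The spectrin gene SPTB was 2.75-fold lower and AHSP, which encodes an alpha-globin chaperone, 2.89-fold lower on 95 and 33 counts. In the list of heme synthesis and iron genes, 1 of 17 was at least 2-fold higher and 1 lower, and the median of -0.26 lay at percentile 11.9. The transferrin receptor gene TFRC was at 918.2 and 346.7 CPM (log2 ratio -1.41) and STEAP3 at -0.69, while ALAS2 was at 0.86 and ALAD at 1.18.

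Hematopoietic transcription factor genes were lower as a list, with a median log2 ratio of -0.57 over 20 genes, below all matched random lists (percentile 0). At least 2-fold lower were 5 of them and 0 were higher. LMO2 was at 95.4 and 23.1 CPM (log2 ratio -2.04), MYC at 610.9 and 220.3 CPM (-1.47, interval -1.53 to -1.42) and MYB at 190.4 and 74.3 CPM (-1.36). RUNX1 (-1.37) and GFI1B (-1.18), chosen after their values were seen, were the others. TAL1 had a ratio of 0.26, ETV6 0.16 and the main erythroid factor gene GATA1, chosen after its value was seen, -0.56. Of 11 measured regulators of hemoglobin switching, MYB was lower and NR2F2 higher (log2 ratio 1.11), SOX6 was at 0.79 and HBS1L at -0.34, and the median of -0.18 lay at percentile 40.5.

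Genes of the integrated stress response, which covers amino acid supply, were lower as a list. All 19 measured members had ratios below 0 on the TMM scale, 7 of them at least 2-fold, with a median of -0.80 (percentile 0); by library totals SLC7A11 was at 0.11 in place of -0.02. The amino acid transporter gene SLC7A5 was at 505.0 and 160.3 CPM (log2 ratio -1.65), DDIT4 at 98.2 and 23.6 CPM (-2.06), and DDIT3 at -0.15. Cholesterol synthesis genes had a median of -0.39 (percentile 0.18) with 0 of 21 past 2-fold; HMGCS1 was at -0.74, SC5D at 0.12 and HSD17B7 at 0.24. Cytosolic ribosomal protein genes had a median of -0.38 (percentile 0.15), from RPL19 and RPL12, both at -0.54, to RPL15 at -0.19 and RPS4X at -0.12, and by library totals the median was -0.25 and RPS4X was at 0.01. DNA replication genes had a median of -0.31 (percentile 1.26), with 0 of 33 past 2-fold; UNG was at -0.73, MCM2 at -0.58 and TYMS at 0.04. Glycolysis genes had a median of -0.28 (percentile 13.9), with HK2 at -1.14 and PFKP at -1.03 against PKM at 0.97 and ENO2 at 1.04. The matched random lists were themselves below 0. Their medians were -0.23 for ribosomal protein, -0.17 for glycolysis, -0.15 for DNA replication and -0.13 for cholesterol synthesis genes. Part of each of these list medians was thus shared by other genes of the same expression level.

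Mitosis genes lay near their control level. Of 28 measured, 0 passed 2-fold, and the median was -0.06 (percentile 90.8), or 0.07 by library totals. BUB1 was at -0.53, BUB3 at -0.27, KIF11 at 0.57 and CENPE at 0.67. Cell cycle inhibitors and p53 target genes had a median of 0.37 (percentile 99.8), with 4 of 22 at least 2-fold higher and 0 lower. CDKN1A, which encodes the inhibitor p21, was 3.44-fold higher (6.50 and 22.3 CPM) and BTG2 2.94-fold (54.2 and 159.4 CPM), while BBC3 was at -0.73 and PLK3 at -0.43. Of 20 DNA damage response genes 0 passed 2-fold, from BLM at -0.55 and XRCC2 at -0.48 to TP53BP1 at 0.45 and ATM at 0.46, and the median of -0.22 lay at percentile 10.5. Heat shock and unfolded protein genes had a median of -0.14 (percentile 77.1). Within them the cytosolic and mitochondrial chaperone genes HSPA8 and HSPD1 were both at -0.65, and the endoplasmic reticulum genes PDIA4 and SDF2L1 at 0.80 and 0.71.

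**Figure D3:**
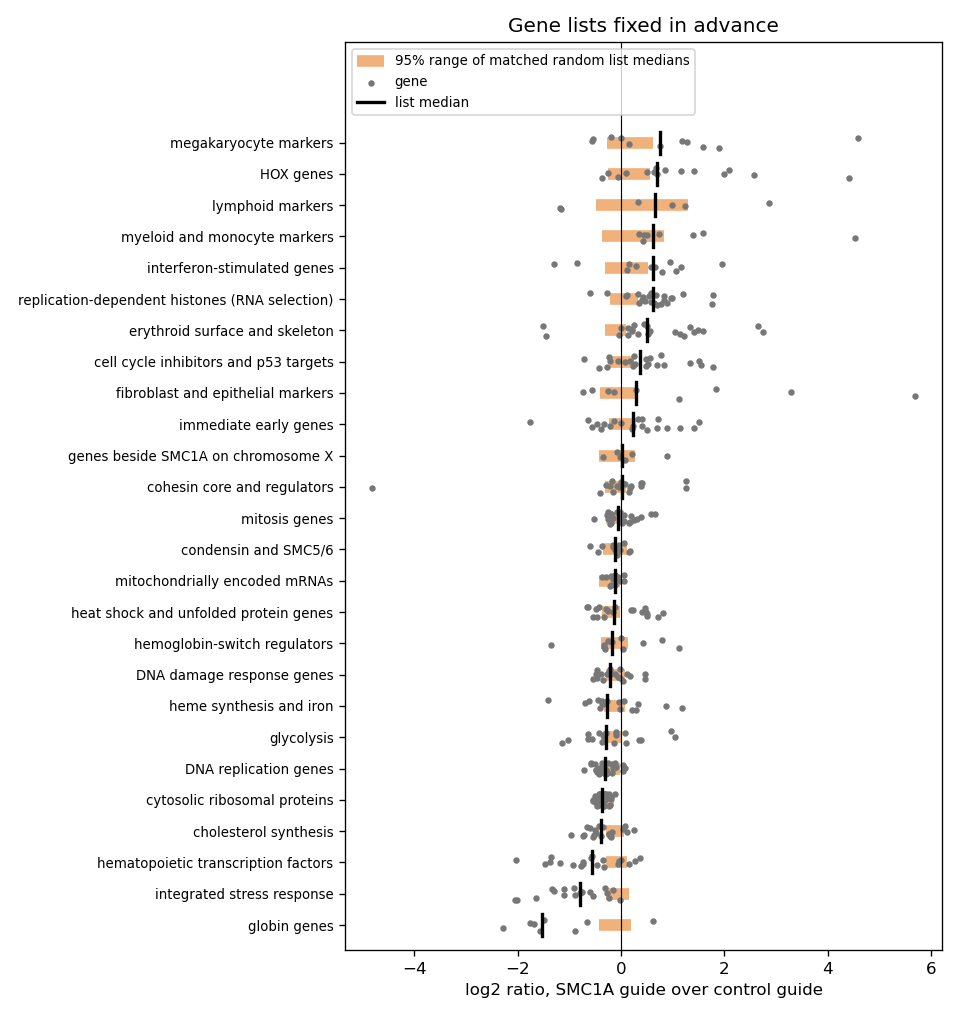
Log2 ratio (SMC1A guide over control guide) of the measured members of 26 gene lists; grey points are genes, black ticks list medians, and orange bars the 95% range of medians of matched random lists. The globin, integrated stress response and transcription factor medians (-1.53, -0.80 and -0.57) lie left of their bars, and the median of red cell surface and skeleton genes (0.51) lies right of its bar.

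Several markers of other blood and tissue cells were higher with the SMC1A guide. Of 11 measured megakaryocyte markers 5 were at least 2-fold higher and 0 lower (median 0.75, percentile 99.1), with TUBB1 at 6.16 and 23.2 CPM, GP6 at 11.8 and 35.5 CPM, CD36 at a log2 ratio of -0.57 and F2R at -0.54. Among 9 fibroblast and epithelial markers (median 0.29, percentile 98.0), 4 were at least 2-fold higher. They include FN1 and COL3A1, which had 2 counts with the control guide and 154 with the SMC1A guide (76.6-fold, counting interval 20.8 to 638.2), while EPCAM was at -0.57 and COL1A2 at -0.73. Myeloid and monocyte markers had a median of 0.62 over the 8 of 20 genes measured (percentile 93.0), with CD33 at 0.74, CYBB at 0.45, LYZ at 0.42 and CD68 at 0.35. Lymphoid markers had a median of 0.66 over the 6 of 15 genes measured (percentile 81.0), with CD3G at 1.24, CD3D at 0.34 and CD52 at -1.16. Matched random lists had medians of 0.12 for megakaryocyte, 0.14 for myeloid and 0.27 for lymphoid markers, against -0.12 for fibroblast and epithelial markers. Part of the megakaryocyte, myeloid and lymphoid medians was thus shared by other genes of the same expression level.

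HOX genes had a median of 0.69 (percentile 99.2, with a median of 0.13 for matched random lists), with 6 of 15 at least 2-fold higher and 0 lower. HOXB6 was at 3.02 and 12.2 CPM (log2 ratio 2.00) and HOXC6 at 1.40, while HOXB9 was at -0.37 and HOXB4 at -0.26. Interferon-stimulated genes had a median of 0.62 over the 12 of 30 listed names that were measured (percentile 98.8), 7 of them with at least 100 counts. The other names had under 20 counts or no row of their own. BST2 was at 99.5 and 222.0 CPM (log2 ratio 1.16), IRF1 at 1.06 and IFITM1 at -1.30. Immediate early genes had a median of 0.23 over 21 genes (percentile 94.5), with NR4A2 at 1.41, DUSP5 at 1.15, JUNB at -0.63 and IER3 at -1.76. Of 53 clustered protocadherin genes, 1 reached 20 counts, PCDHGA6 with 2 and 22 (log2 ratio 2.93, interval 1.43 to 6.58), which was named after its counts were seen.

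Replication-dependent histone genes, whose main transcripts lack a poly(A) tail, had a median log2 ratio of 0.61 over 24 genes (percentile 99.98), with H2BC5 at 1.19, H4C14 at 0.98, H2AC6 at 0.32 and H1-2 at 0.12. This was the same direction as for the erythroid surface, cell cycle inhibitor, megakaryocyte, fibroblast, interferon and HOX lists above. The untailed RNAs RN7SL1 and RN7SL2, chosen after their values were seen, showed no detectable difference, with log2 ratios of 0.14 (-0.18 to 0.47) and -0.07 (-0.36 to 0.21). Mitochondrially encoded mRNAs had a median of -0.13 (percentile 87.9), or 0.00 by library totals, from MT-ND6 at -0.37 and MT-ND2 at -0.30 to MT-ND5 at 0.05 and MT-CO1 at 0.06.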

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

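Removal of the trends with GC content and length or with expression level, and all settings for the reporters, were chosen after seeing the data. The number of genes past 2-fold followed the filter on counts. It was 1361 higher and 518 lower with at least 20 counts, 199 and 140 with at least 500 counts, 3800 and 2714 with no filter, and 343 and 143 when the whole counting interval had to lie past 2-fold. Under the other scalings, prior counts, trend removals and protein-coding genes alone, both counts stayed within 1.5 times the reported ones, from 468 to 766 higher and from 195 to 346 lower. Scaling by library totals moved the dsRed log2 ratio to 0.93, the median log2 ratio of condensin and SMC5/6 to 0.0115, the median log2 ratio of mitosis genes to 0.0743, that of DNA replication genes to -0.18, that of cytosolic ribosomal proteins to -0.25 and the median log2 ratio of mitochondrially encoded mRNAs to 0.0033, a shift built into that scaling. With no filter the protocadherin median was 0, where 1 of 53 members had reached 20 counts. Of 215 list medians computed under alternatives, 209 stayed within the interval of the reported value. Of 828 values for other named genes, 71 left their counting interval, and 0 that were at least 2-fold from the control changed sign. RAD21, CTCF, KDM5C, SLC7A11 and RPS4X, all close to 0, did change sign. The 2 reporters had opposite signs and the SMC1A ratio stayed below -4 under each scaling and prior count. The largest shift of the median ratio was 0.13, too small to turn the sign of such ratios or of any past 2-fold. These signs are therefore no separate check of the differences. No replicate could be left out and no paired analysis was possible because each guide has 1 library. Depth limits genes with few counts, whose counting intervals are wide.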

Other observations

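Tests of unspliced RNA, of the trend with expression level, of the 2 cultures and of the reporters were chosen after their result was seen, and the genes named here were chosen after their values were seen. KIT, a cytokine receptor gene, had 201 and 15 counts (log2 ratio -3.67, interval -4.62 to -3.00). The signalling genes STAT5A and PIM2 were at -1.39 and -1.38, and the cell death gene BCL2L11 at -1.46. ID1 and ID3, which encode inhibitors of helix-loop-helix factors, were at 2.03 and 3.00, the repressor gene BCL6 at 3.63 with 34 and 436 counts, and IFI16 at 3.19.

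Some genes near each other differed in the same direction. On chromosome 11, MS4A3 and MRPL16 had log2 ratios of -3.29 and -1.63. The fatty acid desaturase genes FADS1, FADS2 and FADS3 there had -1.70, -1.16 and -1.25. In the annotation FADS1 lies within the FADS2 span on the opposite strand. FEN1, at -0.34, overlaps FADS2 on the same strand. Whether these overlapping genes share reads was not tested. On chromosome 17, STAT5A and CAVIN1 were at -1.39 and -1.77, with STAT3 between them at -0.43 and STAT5B beside them at 0.03. On chromosome 2, beside HECW2 at 5.83, STK17B was at 0.40 (interval 0.23 to 0.57), while CCDC150 had 408 and 395 counts and the antisense gene HECW2-AS1 had 63 and 62. On chromosome 6, CD24 was at -4.52 and CRYBG1, within the same megabase, at 3.21. ZNF117, at a log2 ratio of 2.13, and ERV3-1, at 41.4 and 190.5 CPM, overlap on the same strand and may share reads, a possibility that the correlation of 0.0475 over adjacent genes that do not overlap leaves open for this pair.

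The first pattern weighed is that genes at least 2-fold higher outnumber those lower, 579 to 263. Counting error alone is argued against, since at most 1 gene was 2-fold higher in any of 100 Poisson redraws of both libraries with no change. Such redraws hold no variation between cultures or from library preparation. Bias from GC content and transcript length is argued against as the whole cause, since 2.24 genes were higher per gene lower once that trend was removed. Genomic DNA is argued against by 381 olfactory receptor genes, which gained 0.083 counts each against a median of 149.5 for the genes that were higher. Unspliced RNA remains open, because the nuclear RNAs MALAT1 and NEAT1 had log2 ratios of 0.43 and 0.35, and so does a trend with expression level, since its removal left 1.35 genes higher per gene lower, under the 1.5 that would argue against it and over the 1 that it would need as the whole cause. Whether depletion of SMC1A or some other difference between the cultures underlies the pattern cannot be told apart with 1 library per guide. The guide sequences are not given in the sources used here. Repression of genes other than SMC1A by the guide itself, CD24 for example, could therefore not be examined.

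The second pattern is the opposite direction of the reporters. Scaling cannot alter the dsRed to d2EGFP ratio within a library, which was 6.61 times higher with the SMC1A guide (95% interval 6.01 to 7.26). A difference in scaling is thus argued against for the change of the reporters relative to each other. The opposite signs are not settled by this ratio, since a common shift beyond the dsRed log2 ratio of 0.80 would give both the same sign. The scalings tried moved the median ratio by at most 0.13. Reads of the blue fluorescent marker or another vector in the d2EGFP row remain open: they can make up at most the 33.7 CPM seen with the SMC1A guide there, but the control library sets no such bound. Positions and enhancers of the reporters are not in the labels, so no biological explanation was tested.

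The third pattern is a weak tendency of adjacent genes to share a direction. Over 10264 adjacent pairs of protein-coding genes Spearman's rho was 0.048, above the highest of 1000 shuffles of gene order within chromosomes (0.039); this is a correlation across genes, which are not independent replicates. Reads shared by overlapping genes are argued against, since 8795 pairs that do not overlap gave 0.0475 against a highest shuffle of 0.042. Without pairs that share a name stem rho was 0.0343, which 3 of 1000 shuffles reached, so tandem families may be part of it. Pairs within 10 kb gave 0.105, which 0 of 1000 shuffles reached, and those 10 to 50 kb apart 0.0533, which 3 of 1000 reached. Those 50 to 100 kb apart gave 0.0436, which 104 of 1000 reached, and those 100 to 250 kb apart -0.0189, which 747 reached. All pairs over 50 kb apart gave 0.0065, which 388 of 1000 reached. The lack of a correlation over 50 kb is what shared promoters or readthrough between close genes would give. Other causes that act only between close genes would give it too and were not weighed. The distances set no sharp limit at 50 kb.

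A few genes were at 0 in one library and well counted in the other. The long non-coding genes ENSG00000238122 and ENSG00000224698, near each other on chromosome 1 and on opposite strands, had 340 and 0 counts with the control guide and 0 and 513 with the SMC1A guide. Whether reads of similar sequence were divided differently between them in the 2 libraries was not tested, so these counts do not show that either gene was switched on or off. The readthrough gene BLOC1S5-TXNDC5 had 0 and 269 counts.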
